A study of Homo sapiens with 40 samples.

How the data were processed

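The series holds 40 libraries of polyadenylated RNA, 5 for each of 4 cell lines at each of 2 implantation sites. Each library was supplied as its own table of 30727 human genes under Entrez identifiers. The count column holds whole numbers of reads that align uniquely to a gene model, per the file headers, and had not been normalized by the authors. The value column holds RPKM adjusted by a size factor per library, computed by the authors, per the file headers. Reads were aligned with GSNAP and the builds GRCh38 and GRCm38 are named, per the submitters' processing notes, which give no versions and no role for the mouse build. No mouse genes are in the tables, so the removal or retention of mouse reads is not known. Strand was not stated. The size factors recovered from counts and RPKM ran from 0.245 to 1.568, over 8675 genes, with a largest log deviation between genes of 8e-15.

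Counts were analysed, so a fallback planned for tables without counts was not needed. The RPKM values served only to recover those size factors and relative gene-model lengths. Of the identifiers, 27814 were matched to a RefSeq gene symbol, and the 2913 others, with 0.441% of counts, stayed under their identifiers. Transcripts of GENCODE 29 gave the GC of genes. Totals ran from 4.3 to 26.9 M counts per library with a median of 20.95 M, and at these totals 3 counts equal the CPM floor used for genes near 0. Among 80 pairs of replicates the lowest chi-square per gene was 6.69, so no library duplicates another of its group up to counting noise. Pairs of libraries from different groups were not compared in this way.

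Within each line, liver was compared with colon by edgeR 4.0.16 in R 4.3.3. Settings were TMM scaling, filterByExpr (minimum count 10, minimum total 15), a robust quasi-likelihood fit and Benjamini-Hochberg adjustment with a threshold of 0.05. Levels are CPM on TMM-scaled library sizes, with a prior count of 2 where logs were taken. A fit of 8 groups to all 40 libraries gave the mean site effect with equal weight per line, the difference of the site effect between lines (3 degrees of freedom), and each line against the mean of the others, also tested against a log2 fold change of 1 with glmTreat. Pearson correlations between site effects were computed across genes, which are not independent replicates.

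In advance, 40 gene lists were compiled. They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, where at least 3 members were measured. The lists hold 602 entries and 583 distinct genes, of which 3 (MUC2, HLA-B and HLA-E) have no values in the tables and were not used here. Summed CPM of 8 lists of cell type markers were compared between sites by exact two-sided permutation tests.

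Genes were named by a rule. For each line it takes the 8 largest changes per direction among genes past the threshold with a mean of at least 2 log2 CPM and no overlap between sites. It adds up to 4 members with the smallest p of each list that passed camera or stands for another cell type. For the mean it takes the 10 smallest p per direction with the same sign in each line, for differences between lines the 10 smallest p, and for each line against the others the 8 largest per direction and 3 members per list. The text names part of these. The samples, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

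Alternatives were DESeq2 1.42.0 as scaling and as test, limma-voom with and without quality weights, other expression filters, the 40-library fit for each line, the replicate number as a block, removal of cell type genes, a hepatocyte score as a covariate, and leaving out each library, replicate number or line. Others were chosen after seeing the data. They are the removal of each library's trend with gene-model length and transcript GC (splines with 4 degrees of freedom), the authors' size factors, removal of the 13 mitochondrially encoded genes, and removal of 5 doubted libraries (DLD1 liver replicate 5, Ls180 colon replicate 2 and liver replicate 1, MDST8 liver replicates 1 and 2). Labels were also permuted in 100 of the 126 splits of each line and in 36 splits of all libraries. Within groups of 5, a library was set apart when its gap to the nearest other, over the range, exceeded Dixon's 0.71.

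The procedure was tested on simulated data with 200 changed genes, drawn only from genes with a mean of at least 2 log2 CPM. Of genes changed 2-fold, 88.1% were recovered in RKO, 59.7% in DLD1, 83.6% in Ls180, 64.2% in MDST8, 86.6% for the mean and 52.2% for differences between lines. Of genes changed 1.5-fold the shares were 65.7%, 29.9%, 32.8%, 13.4%, 85.1% and 9%. False calls made up 1.4% to 6.5% of calls. With only the length and GC trends of DLD1 put in, 166 genes were called, and 0 after the trend was removed. A hypoxia list raised 1.5-fold was the only list called in each line. Genes were drawn independently in these simulations, so they do not test camera's preset correlation. For the same reason the shares recovered need not hold where genes vary together within a library, nor for genes at lower levels, which were not changed. Other splits of the real libraries gave up to 13 lists in RKO, 17 in DLD1, 22 in Ls180 and 15 in MDST8. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and figures.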

Results

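Gene expression was measured by sequencing polyadenylated RNA from tumours that 4 human colorectal cancer cell lines, RKO, DLD1, Ls180 and MDST8, had formed in NSG mice, a strain without functional lymphocytes. Each line had been placed in the colon, by way of an induced rectal prolapse, or in the liver, by hydrodynamic injection into the tail vein, so organ and route of implantation cannot be separated here. The 8 groups held 5 libraries each, 40 in all. The labels name replicate samples and not separate animals, so p-values measure the spread between these samples, which may be technical. Library totals ran from 4.3 to 26.9 M (mega) counts on human genes, with a median of 20.95 M. In RKO they averaged 20.4 ± 6.51 M (mean ± SD, n = 5) in colon and 22.02 ± 1.91 M in liver, and in DLD1 21.1 ± 7.81 and 11.5 ± 5.07 M. In Ls180 they averaged 20.7 ± 2.31 M in colon and 16.7 ± 4.09 M in liver, and in MDST8 24.7 ± 0.54 and 19.02 ± 1.7 M. Levels are given as counts per M counts (CPM), as mean ± SD over 5 libraries, and fold changes as log2 of liver over colon ± SE. Adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

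The first question was how the same cells differed between liver and colon. In DLD1 tumours, camera placed the list of interferon-induced genes higher in liver and that of intestinal identity lower, but neither passed with an estimated correlation (adjusted p = 0.96 for each). IFI6 (Entrez 2537), an interferon-induced mitochondrial protein, averaged 203 ± 134 CPM in liver and 21.0 ± 4.38 in colon (log2 fold change 3.27 ± 0.50, adjusted p = 0.0014 by edgeR). The ubiquitin-like modifier ISG15 rose from 52.0 ± 6.95 to 180 ± 88.7 CPM, and the antiviral GTPase MX1 from 9.81 ± 0.79 to 32.1 ± 19.8 CPM. GPA33 (Entrez 10223), a surface antigen of intestinal epithelium, fell by 2.35 ± 0.31 on the log2 scale (adjusted p = 7.47e-04 by edgeR), and the intestinal cadherin CDH17 dropped from 220 ± 49.6 to 85.4 ± 41.8 CPM.

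Of the 19 measured members of the interferon list, 8 rose over all genes tested and 12 when adjusted over the list alone, with a median log2 fold change of 0.86. Camera gave an adjusted p = 0.0038 for the list, and an adjusted p = 0.96 with an estimated correlation. IFIT1 and IFI27 also rose, by 2.26 ± 0.50 and 3.14 ± 0.71. The list's mean log2 CPM lay above every colon library in 4 of the 5 liver libraries and below every colon library in 1, liver replicate 4. Of the 12 measured genes of intestinal identity, 7 fell (7 also when adjusted over the list alone, median -0.49, camera adjusted p = 0.0019, and adjusted p = 0.96 with an estimated correlation). They include LGALS4, a galectin of the gut epithelium (-1.40 ± 0.29), and HNF4A, a transcription factor of gut and liver epithelium (-0.42 ± 0.12). SLC26A2, a sulfate transporter of colonocytes, fell by 0.57 ± 0.16.

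Among other large DLD1 differences, STRA6, the receptor for retinol-binding protein, was at 0.77 ± 0.42 CPM in colon and 9.53 ± 7.38 in liver. FMOD, a collagen-binding proteoglycan, rose from 5.32 ± 0.64 to 23.4 ± 8.78 CPM, and the retinoid-responsive gene RARRES1 from 2.23 ± 0.43 to 7.90 ± 3.51. The ferroxidase HEPH fell from 12.2 ± 4.23 to 0.35 ± 0.55 CPM, the peptidase DPP4 from 8.91 ± 3.55 to 0.85 ± 0.75. The purinergic receptor P2RY1 fell by 2.99 ± 0.31 on the log2 scale and the membrane mucin MUC13 by 2.94 ± 0.36. In the hypoxia list 3 of 23 measured members fell (2 when adjusted over the list alone, median -0.42, camera adjusted p = 0.021, and adjusted p = 0.96 with an estimated correlation). With the length and GC trend removed the list median was -0.40 and 1 member was still called lower. The glycolytic genes ALDOC and PFKFB3 fell by 1.42 ± 0.36 and 0.98 ± 0.26. The hypoxia call ended without colon replicate 2 (camera adjusted p = 0.18), liver replicate 1 (0.18) or liver replicate 3 (0.12). Without liver replicate 5 the liver mean of HEPH was 0.11 CPM, and without liver replicate 4 that of DPP4 was 0.56. In DLD1 liver libraries 3 counts give 0.181 to 0.699 CPM. Both these means and the 0.35 CPM of HEPH lie within or under that range, so the size of these falls is uncertain.

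Lists of oxidative phosphorylation and of the ribosome were also higher in DLD1 liver tumours by camera. In the oxidative phosphorylation list 11 of 24 members rose (12 when adjusted over the list alone, median 0.41, camera adjusted p = 7.2e-06, and adjusted p = 0.96 with an estimated correlation). COX7B of complex IV was at 72.2 ± 5.30 CPM in colon and 141 ± 21.6 in liver. In the ribosomal protein list 8 of 24 rose (11 when adjusted over the list alone, median 0.36, camera adjusted p = 2.7e-05, and adjusted p = 0.96 with an estimated correlation). RPL13 was at 650 ± 36.3 CPM in colon and 1004 ± 108 in liver. These short genes moved with gene length. Across genes the DLD1 fold changes had a Spearman correlation of -0.63 with length, against -0.13, -0.21 and -0.17 in RKO, Ls180 and MDST8. Of 5 equal groups of genes by length, the shortest had 1016 higher and 60 lower calls and the longest 30 higher and 935 lower. With each library's length and GC trend removed, the list medians were 0.04 for oxidative phosphorylation and -0.11 for ribosomal proteins, and camera's adjusted p was 0.48 and 0.43.

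**Figure D1:**
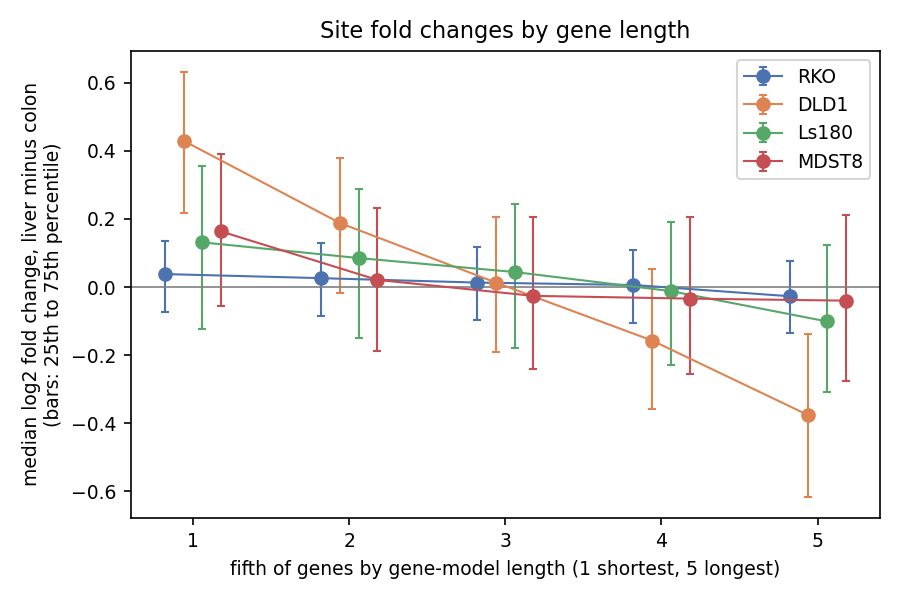
Median log2 fold change (liver minus colon, y axis) of genes in 5 equal groups by gene-model length (x axis, 1 shortest, 5 longest) for the 4 lines, with bars from the 25th to the 75th percentile of genes. In DLD1 the medians fall from 0.43 in the shortest group to -0.38 in the longest.

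Over all 15168 genes tested in DLD1, 1724 were higher and 1830 lower in liver, 3554 in total, of which 700 differed at least 2-fold. The total was 1964 with the length and GC trend removed (1311 of them among the 3554), 1206 with the length trend alone removed, 1709 with a hepatocyte marker score as a covariate, 2025 without colon replicate 1 and 5527 without liver replicate 5, whose mitochondrial share was 16.1% of counts.

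In Ls180 tumours, most hypoxia genes were higher in liver. Camera also placed the intestinal identity list higher, and the mesenchymal and YAP target lists lower, though most of their members did not pass the threshold singly. With an estimated correlation none of these lists passed (adjusted p = 0.48 for hypoxia, 0.54 for intestinal identity and YAP targets, and 0.65 for mesenchymal genes). The mitophagy receptor BNIP3 rose from 30.7 ± 3.01 to 103 ± 22.2 CPM (log2 fold change 1.75 ± 0.15, adjusted p = 3.56e-04 by edgeR), and the collagen prolyl hydroxylase P4HA1 from 119 ± 15.6 to 411 ± 86.2 CPM. LDHA, which makes lactate from pyruvate, rose from 1143 ± 124 to 2464 ± 317 CPM. FABP1, a fatty-acid-binding protein of liver and gut, was at 2.95 ± 3.15 CPM in colon and 77.1 ± 50.5 in liver. Without colon replicate 3 its colon mean was 1.63 CPM. The receptor tyrosine kinase AXL fell from 40.2 ± 29.2 to 3.96 ± 1.31 CPM.

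Of the 24 hypoxia genes, 21 rose in Ls180 (22 when adjusted over the list alone, median 1.01, camera adjusted p = 8.3e-19, and adjusted p = 0.48 with an estimated correlation), MXI1, a MYC antagonist, among them (1.04 ± 0.10). In the glycolysis list 8 of 13 rose (9 when adjusted over the list alone, median 0.47, camera adjusted p = 1e-05, and adjusted p = 0.54 with an estimated correlation). Hexokinase HK2 (1.19 ± 0.14) and the isomerase TPI1 (0.51 ± 0.09) were among them. Of 13 genes of intestinal identity 6 rose (7 when adjusted over the list alone, median 0.63, camera adjusted p = 8.3e-05, and adjusted p = 0.54 with an estimated correlation). CDH17 went from 344 ± 42.8 to 680 ± 116 CPM, GPA33 from 386 ± 95.8 to 797 ± 53.5, and the intestinal transcription factor CDX1 from 141 ± 27.6 to 219 ± 27.6.

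Chaperone and ribosome lists were higher in Ls180 liver tumours as well. In the unfolded protein response list 6 of 15 rose (9 when adjusted over the list alone, median 0.51, camera adjusted p = 2.8e-04, and adjusted p = 0.65 with an estimated correlation). The endoplasmic reticulum chaperones HSP90B1 and HSPA5 rose by 1.00 ± 0.21 and 0.97 ± 0.23. In the heat shock list 5 of 11 rose (7 when adjusted over the list alone, median 0.54, camera adjusted p = 8.3e-05, and adjusted p = 0.54 with an estimated correlation). The mitochondrial chaperonins HSPE1 and HSPD1 rose by 0.73 ± 0.11 and 0.91 ± 0.19. Ribosomal proteins rose in 17 of 24 cases (19 when adjusted over the list alone, median 0.46, camera adjusted p = 1.6e-09, and adjusted p = 0.54 with an estimated correlation). RPL27 rose by 0.67 ± 0.12 and RPS3 by 0.60 ± 0.13. Oxidative phosphorylation genes rose in 6 of 24 cases (6 when adjusted over the list alone, median 0.24, camera adjusted p = 5.4e-04, and adjusted p = 0.65 with an estimated correlation), but camera's adjusted p was 0.32 with the length and GC trend removed.

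Among the lists that were lower, 3 of 9 measured mesenchymal genes fell and 1 rose (6 and 1 when adjusted over the list alone, median -1.39, camera adjusted p = 0.019, and adjusted p = 0.65 with an estimated correlation). AXL, VIM and FN1 fell, and the actin-binding CALD1 rose by 0.71 ± 0.17. Markers of other cell types moved in both directions. The fibroblast collagen COL3A1 fell from 1.22 ± 0.26 to 0.02 ± 0.03 CPM, in liver under what 3 counts give. The smooth muscle myosin MYH11 fell by 0.90 ± 0.23 on the log2 scale, whereas the endothelial gene ERG rose by 1.69 ± 0.41. The smooth muscle list summed to 102 ± 22.2 CPM in colon and 67.4 ± 9.41 in liver (exact permutation test, p = 0.0317, adjusted p = 0.145). The endothelial list went from 11 ± 1.85 to 19.5 ± 4.94 CPM (exact permutation test, p = 0.0159, adjusted p = 0.0847). The fibroblast list was at 26.1 ± 4.81 CPM in colon and 21.6 ± 17.6 in liver (exact permutation test, p = 0.603, adjusted p = 0.804). A part from other cells is thus not excluded. Of 12 YAP targets 4 fell (7 when adjusted over the list alone, median -0.84, camera adjusted p = 9.8e-05, and adjusted p = 0.54 with an estimated correlation). They include the matrix protein CCN1 (-1.93 ± 0.51), the transcription factor TEAD1 (-0.59 ± 0.15) and the kinase LATS2 (-0.93 ± 0.26). Of 14 NF-kB targets 3 fell (5 when adjusted over the list alone, median -1.15, camera adjusted p = 0.0094, and adjusted p = 0.77 with an estimated correlation). The chemokine CXCL1 was at 149 ± 153 CPM in colon and 19.6 ± 11.3 in liver, and its call ended without colon replicate 1, 3 or 4 or liver replicate 2, 3, 4 or 5. Of 13 immediate early genes 3 fell (6 when adjusted over the list alone, median -0.63, camera adjusted p = 0.0084, and adjusted p = 0.65 with an estimated correlation). The phosphatase DUSP1 fell by 1.53 ± 0.37. Of 13 p53 targets 3 fell (4 when adjusted over the list alone, median -0.34, camera adjusted p = 0.012, and adjusted p = 0.65 with an estimated correlation), TP53INP1 by 1.14 ± 0.20. In the Wnt target list, APCDD1 fell from 63.6 ± 29.7 to 4.78 ± 5.67 CPM and NOTUM from 2.32 ± 1.85 to 0.28 ± 0.24, whereas CRIPTO, a ligand co-receptor, rose from 11.5 ± 2.40 to 19.0 ± 3.17. Without liver replicate 4 the liver mean of APCDD1 was 2.37 CPM. The list as a whole gave 1 higher and 4 lower of 13 (1 and 6 when adjusted over the list alone, median -0.34, camera adjusted p = 0.048, and adjusted p = 0.65 with an estimated correlation). Its call ended with the length and GC trend removed (0.15), without the 2 libraries nearest the other site (0.13), with DESeq2's size factors (0.05), by directional fry (0.082) and without colon replicate 1 (0.072), 2 (0.11) or 5 (0.072) or liver replicate 2 (0.054), 3 (0.10) or 5 (0.06). Without colon replicate 4 the mesenchymal and NF-kB calls ended (0.06 each), without colon replicate 1 the NF-kB call (0.051), and without liver replicate 3 the p53 call (0.064).

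Further large Ls180 differences included the receptor tyrosine kinase KIT (Entrez 3815), which rose by 3.91 ± 0.45 on the log2 scale, and the homeobox gene EVX1, at 1.23 ± 0.85 CPM in colon and 11.2 ± 6.34 in liver. The glucuronosyltransferase UGT1A1 rose from 10.3 ± 2.72 to 96.3 ± 57.7 CPM, but genes of the UGT1A locus share exons, so reads cannot be assigned to 1 of them with certainty. CD109, a surface antigen that binds TGF-beta, fell from 124 ± 54.2 to 4.37 ± 4.13 CPM, the caveolar protein CAV1 from 47.1 ± 55.6 to 2.12 ± 2.24, and the collagen COL12A1 from 19.8 ± 17.7 to 0.20 ± 0.31. Without colon replicate 4 the colon means of CAV1 and COL12A1 were 22.7 and 12.3 CPM. Without liver replicate 4 the liver mean of COL12A1 was 0.07 CPM, and without liver replicate 1 that of CD109 was 2.80. In Ls180 liver libraries 3 counts give 0.134 to 0.257 CPM, so both liver means of COL12A1 lie within or under that range.

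Over the 15146 genes tested in Ls180, 1186 were higher and 1055 lower in liver, 2241 in total and 661 at least 2-fold. In the fit to all 40 libraries the split was 1143 higher and 1930 lower. With a hepatocyte marker score as a covariate the total was 45, with 49 of 56 named genes losing their call. The strict hepatocyte list behind this score summed to 4.57 ± 2.2 CPM in colon and 2.09 ± 0.42 in liver. It was lower in each liver library than in any colon library, so the score can take up the site effect itself. The lower total is thus no sign of hepatocyte reads in liver tumours. Colon replicate 2, whose mitochondrial share was 7.27% of counts, and liver replicate 1, at 2.47%, lay between the sites, at 0.57 and 0.47 on an axis from the mean of the other colon libraries (0) to that of the other liver libraries (1), and without both the total was 5709. Leaving out a single library gave 952, 4169, 908, 1161 and 1228 genes for colon replicates 1 to 5 and 3387, 996, 1088, 1482 and 996 for liver replicates 1 to 5.

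In MDST8 tumours, most NF-kB targets and antigen presentation genes were lower in liver, and camera placed the TGF-beta and BMP target list higher. With an estimated correlation none of these lists passed (adjusted p = 0.28 for each). The cytokine IL1B was at 74.5 ± 82.4 CPM in colon and 2.64 ± 2.20 in liver, and TNFAIP3, a feedback inhibitor of NF-kB, at 71.9 ± 31.7 and 17.2 ± 1.60 (log2 fold change -2.06 ± 0.27, adjusted p = 0.0023 by edgeR). The immunoproteasome subunit PSMB9 fell from 57.0 ± 9.90 to 21.6 ± 3.33 CPM. ID1 (Entrez 3397) and ID3, inhibitors of helix-loop-helix transcription factors induced by BMP signalling, rose from 2.40 ± 0.95 to 35.0 ± 16.4 and from 17.8 ± 8.14 to 138 ± 38.5 CPM. Without colon replicate 5 the colon mean of IL1B was 38.7 CPM, and without liver replicate 5 its liver mean was 1.66.

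Of 14 measured NF-kB targets, 13 fell in MDST8 (13 when adjusted over the list alone, median -1.93, camera adjusted p = 2.5e-11, and adjusted p = 0.28 with an estimated correlation). NFKBIA, which encodes an inhibitor of NF-kB, fell by 1.40 ± 0.24. Of 11 antigen presentation genes 10 fell (11 when adjusted over the list alone, median -0.95, camera adjusted p = 6.6e-10, and adjusted p = 0.28 with an estimated correlation). The peptide transporter TAP1 fell by 1.01 ± 0.18, PSMB8 by 0.72 ± 0.11 and HLA-F by 2.63 ± 0.37. Of 21 interferon-induced genes 7 fell (11 when adjusted over the list alone, median -1.002, camera adjusted p = 3.1e-06, and adjusted p = 0.46 with an estimated correlation). The nucleotide kinase CMPK2 fell from 54.4 ± 6.90 to 19.6 ± 6.92 CPM and the RNA sensor IFIH1 from 9.91 ± 6.61 to 1.78 ± 0.70. Of 8 acute phase and STAT3 genes 3 fell (6 when adjusted over the list alone, median -0.83, camera adjusted p = 0.004, and adjusted p = 0.28 with an estimated correlation). Complement C3 was at 91.4 ± 141 CPM in colon and 1.499 ± 0.67 in liver, and BCL3 fell by 1.13 ± 0.25. IL6 (Entrez 3569), with 17.5 ± 24.9 CPM in colon, had 0.06 ± 0.08 in liver, below the 0.143 to 0.178 CPM that 3 counts give in these liver libraries. Colon replicate 5 had the highest colon levels of C3 and IL6, and without it the means were 29.3 ± 30.1 CPM for C3 and 6.73 ± 7.67 for IL6 (n = 4).

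In the TGF-beta and BMP target list 6 of 13 genes rose and 2 fell (8 and 3 when adjusted over the list alone, median 0.86, camera adjusted p = 0.0056, and adjusted p = 0.28 with an estimated correlation). SMAD7, an inhibitor of the pathway, rose by 1.22 ± 0.16, and the matrix gene LTBP2 fell from 141 ± 34.7 to 41.8 ± 16.2 CPM. Of 24 proliferation genes 4 fell (8 when adjusted over the list alone, median -0.25, camera adjusted p = 1.8e-04, and adjusted p = 0.40 with an estimated correlation), all 4 of them mitotic genes, KIF20A (-0.76 ± 0.11), PLK1 (-0.67 ± 0.15), TPX2 and AURKB. The glycolysis list had 2 of 13 lower (7 when adjusted over the list alone, median -0.40, camera adjusted p = 0.0051, and adjusted p = 0.36 with an estimated correlation) and the hypoxia list 4 of 23 (6 when adjusted over the list alone, median -0.20, camera adjusted p = 0.014, and adjusted p = 0.40 with an estimated correlation). The angiogenic factor VEGFA was at 21.9 ± 5.64 CPM in colon and 8.55 ± 2.71 in liver. The ribosomal protein list passed camera (median 0.39, adjusted p = 4.3e-04, and adjusted p = 0.67 with an estimated correlation) with 0 of 24 members past the threshold by edgeR, also when adjusted over the list alone. Immediate early genes were split, EGR1 falling by 1.47 ± 0.36 and the antiproliferative BTG2 rising by 1.14 ± 0.17 (1 of 15 higher and 2 lower, 1 and 4 when adjusted over the list alone, median -0.30, camera adjusted p = 0.049, and adjusted p = 0.28 with an estimated correlation). Of the lists for other cell types, 2 of 6 endothelial genes fell, ROBO4 and PECAM1 (4 when adjusted over the list alone, camera adjusted p = 0.0082, and adjusted p = 0.29 with an estimated correlation), and 1 of 3 macrophage genes, CSF1R (1 when adjusted over the list alone, camera adjusted p = 0.049, and adjusted p = 0.36 with an estimated correlation). The immediate early call ended with the replicate number as a block (0.054), with the length and GC trend removed (0.091), without colon replicate 3 (0.071) or 4 (0.081) and without liver replicate 2, 3, 4 or 5 (0.06, 0.062, 0.087 and 0.079). The macrophage call ended with the trend removed (0.086) and without colon replicate 2 (0.057) or 5 (0.10) or liver replicate 3 (0.13) or 4 (0.087). PECAM1 averaged 0.152 CPM in liver, within the 0.143 to 0.178 CPM that 3 counts give there.

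Among the largest MDST8 increases, the receptor phosphatase PTPRZ1 was at 0.04 ± 0.05 CPM in colon, under what 3 counts give there, and at 79.9 ± 99.1 in liver. Others were in KANK4, a cytoskeletal adaptor (0.17 ± 0.04 CPM in colon, 10.9 ± 3.54 in liver), the peptide transporter SLC15A1 (0.35 ± 0.08 and 9.47 ± 6.20), the matrix protein HMCN1 (0.59 ± 0.22 and 14.4 ± 8.17) and the adhesion molecule MCAM (0.32 ± 0.19 and 7.79 ± 4.93). Among genes that fell were TNFSF10, a death receptor ligand (20.3 ± 23.3 and 0.35 ± 0.34 CPM), the neuropeptide GAL (61.8 ± 61.8 and 1.58 ± 2.26) and the smooth muscle actin ACTG2 (189 ± 120 and 4.65 ± 3.69). Without colon replicate 2 the colon means were 10.2 CPM for TNFSF10 and 35.9 for GAL. The liver means were 0.21 for TNFSF10 without liver replicate 5, 0.58 for GAL without liver replicate 4 and 46.9 for PTPRZ1 without liver replicate 2.

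Over the 14953 genes tested in MDST8, 652 were higher and 618 lower in liver, 1270 in total and 640 at least 2-fold. DESeq2 called 2475, the fit to all 40 libraries 2874, and edgeR with the length and GC trend removed 1952. Liver replicates 1 and 2 had mitochondrial shares of 13.5% and 8.17%, against 1.84% to 2.89% in colon, and without both the total was 844, with the macrophage, hypoxia, immediate early, ribosomal and acute phase lists no longer past camera's threshold. Of 47 named genes 22 lost their call without both, among them IL1B, IL6, C3, GAL, ACTG2, IFIH1, BCL3, EGR1, PLK1, AURKB, ROBO4, PECAM1 and CSF1R, all with the direction kept. Leaving out a single library gave 772, 682, 807 and 646 genes for colon replicates 1 to 4, 799 for liver replicate 1 and 2629 for liver replicate 5.

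**Figure D2:**
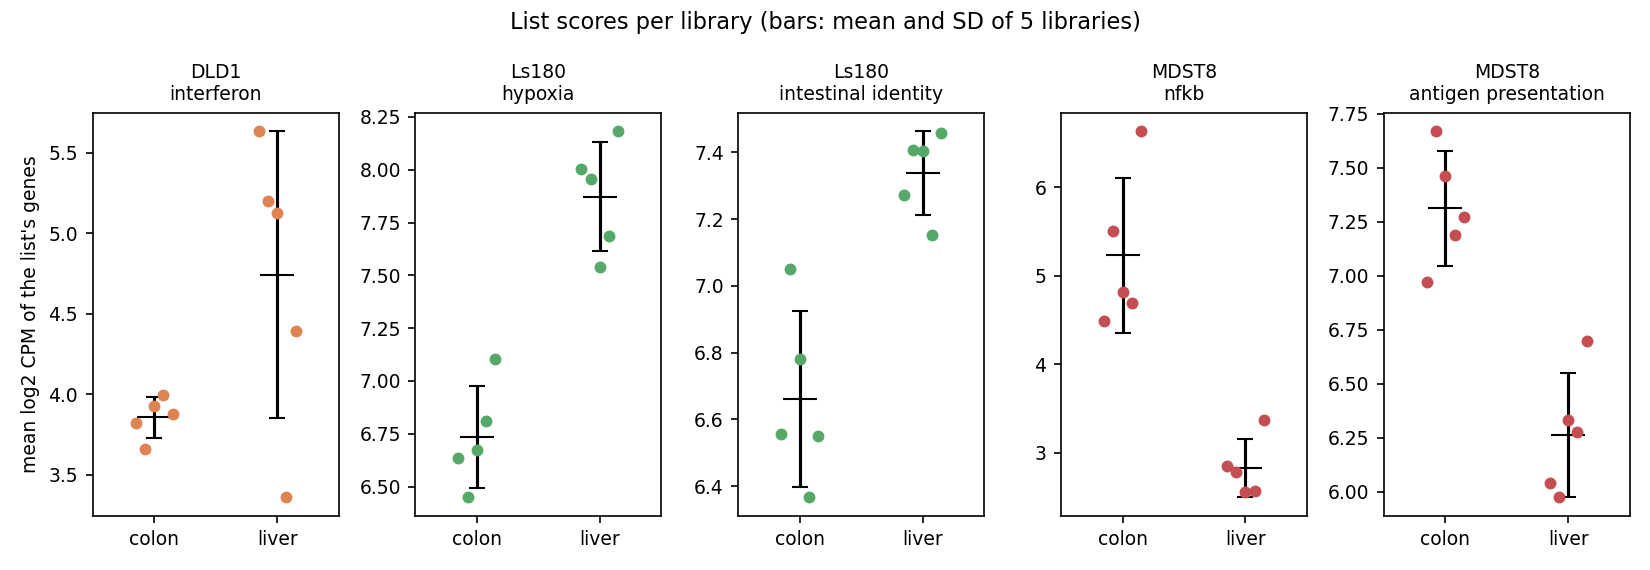
Mean log2 CPM of a gene list (y axis) in each library of colon and liver tumours for 5 lists of 3 lines; points are libraries, and the bars are the mean and SD of 5 libraries. In Ls180 hypoxia, Ls180 intestinal identity and both MDST8 lists all 5 liver libraries lie on one side of every colon library, and in DLD1 interferon 4 liver libraries lie above and 1 below them.

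In RKO tumours no gene passed the threshold in edgeR's quasi-likelihood test over 14205 genes, 1775 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0688. DESeq2 called 266 genes (130 higher, 136 lower), limma-voom 0 and the edgeR fit to all 40 libraries 23. TAGLN, an actin-binding protein of smooth muscle, was at 262 ± 92.4 CPM in colon and 61.6 ± 33.9 in liver (adjusted p = 0.156 by edgeR). Camera placed NF-kB targets low (median -0.82, adjusted p = 4.5e-05, and adjusted p = 0.67 with an estimated correlation). CXCL8 was at 49.4 ± 40.5 CPM in colon and 7.38 ± 8.88 in liver (4.36 without liver replicate 1). Camera also placed low interferon-induced genes (median -0.30, adjusted p = 7.4e-04, and adjusted p = 0.66 with an estimated correlation) and cholesterol synthesis genes (median -0.27, adjusted p = 0.0012, and adjusted p = 0.92 with an estimated correlation). LSS was at 148 ± 31.5 CPM in colon and 101 ± 24.4 in liver. Heat shock genes were placed high (median 0.28, adjusted p = 0.001, and adjusted p = 0.66 with an estimated correlation). HSPD1 was at 477 ± 36.9 and 629 ± 54.4 CPM. Of the members of these lists, 0 passed over all genes, and 3 of 11 NF-kB, 5 of 17 interferon, 0 of 24 cholesterol and 6 of 11 heat shock genes passed when adjusted over the list alone. Leaving out colon replicate 4 or liver replicate 3 gave 1 gene, and no other single library changed the count of 0.

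**Figure D3:**
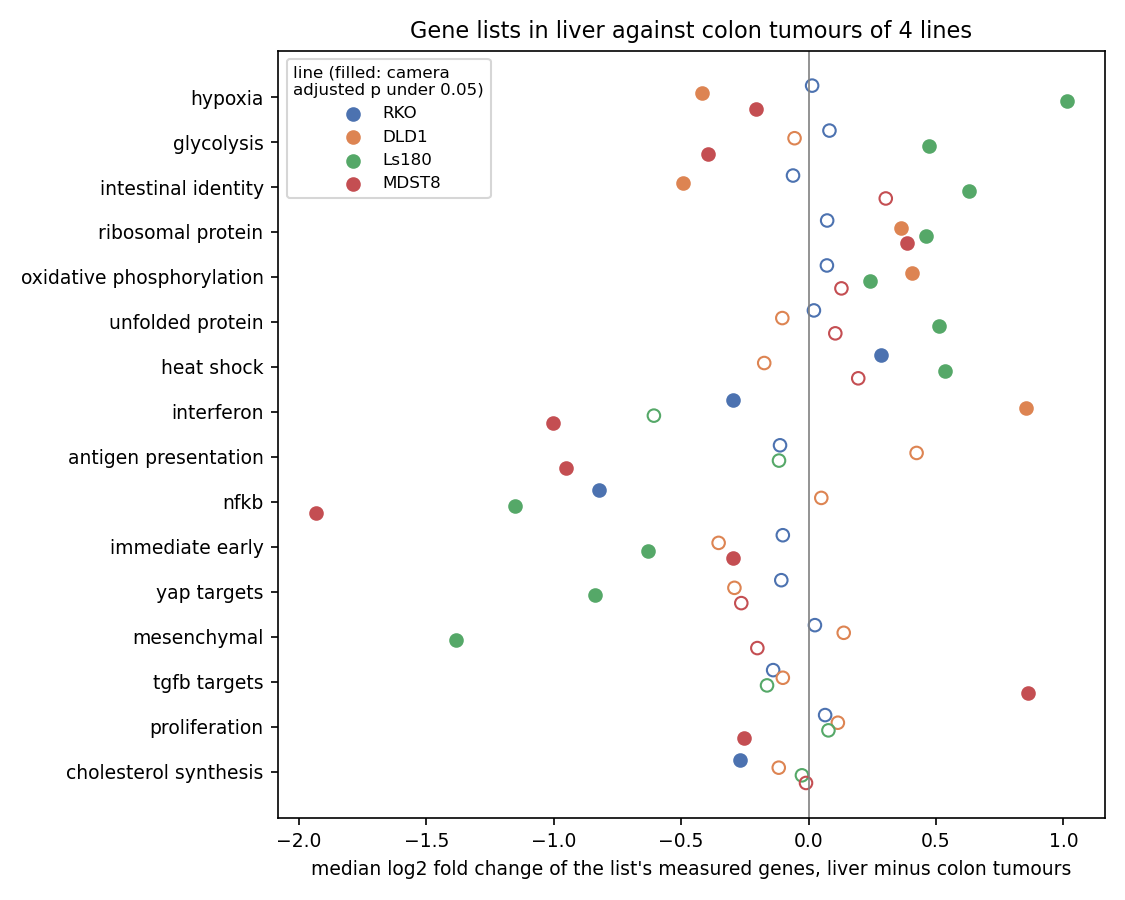
Median log2 fold change (x axis, liver minus colon) of the measured genes of 16 gene lists (y axis) in 4 lines; filled points passed camera at an adjusted p under 0.05 with the preset correlation, open points did not. The hypoxia median is 1.01 in Ls180 and -0.42 in DLD1, and the NF-kB median is -1.93 in MDST8.

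The next question was whether the lines shared a response to the site. Averaged over the 4 lines with equal weight, camera placed the lists of NF-kB targets, immediate early genes and YAP targets lower in liver, and those of oxidative phosphorylation and the ribosome higher. With an estimated correlation none of these passed (adjusted p = 0.47 for each), and oxidative phosphorylation did not pass with the length and GC trend removed (0.13). The chemokine genes CXCL3 and CXCL8 fell by 2.17 ± 0.35 and by 2.29 ± 0.44 on the log2 scale, TNFAIP3 fell by 1.26 ± 0.21 (adjusted p = 3.26e-05 by edgeR), and AXL fell by 1.03 ± 0.18. Of 15 NF-kB targets 12 fell (14 when adjusted over the list alone, median -1.13, camera adjusted p = 1.1e-07, and adjusted p = 0.47 with an estimated correlation). Of 15 immediate early genes 9 fell (9 when adjusted over the list alone, median -0.30, camera adjusted p = 0.0014, and adjusted p = 0.47 with an estimated correlation). EGR1 (-0.71 ± 0.14), KLF6 (-0.57 ± 0.12) and NR4A1 (-0.70 ± 0.14) were among them. Of 13 YAP targets 10 fell (11 when adjusted over the list alone, median -0.48, camera adjusted p = 4.8e-05, and adjusted p = 0.47 with an estimated correlation). TEAD1 fell by 0.45 ± 0.07. Of 11 antigen presentation genes 4 fell (5 when adjusted over the list alone, camera adjusted p = 0.045, and adjusted p = 0.79 with an estimated correlation). This call ended without replicate number 3, 4 or 5 of every group (0.074, 0.13 and 0.064), without the 5 doubted libraries (0.13) and with DESeq2's size factors (0.051). HLA-F fell by 0.72 ± 0.12 and the class I regulator NLRC5 by 0.52 ± 0.14. Within single lines, YAP targets passed camera only in Ls180 and antigen presentation only in MDST8. Immediate early genes passed in Ls180 and MDST8, and NF-kB targets in RKO, Ls180 and MDST8 but not in DLD1. Oxidative phosphorylation passed in DLD1 and Ls180, and ribosomal proteins in DLD1, Ls180 and MDST8. A large change in 1 line can carry such a mean. HLA-F went from 22.9 to 3.66 CPM in MDST8, and AXL from 40.2 to 3.96 CPM in Ls180. Of 36 genes named for the mean, 3 lost their call without Ls180, 2 without MDST8, 1 without RKO and 0 without DLD1.

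Ribosomal proteins rose in 19 of 24 cases on average (23 when adjusted over the list alone, median 0.31, camera adjusted p = 7.4e-12, and adjusted p = 0.47 with an estimated correlation). Oxidative phosphorylation genes rose in 15 of 24 and fell in 1 (15 and 1 when adjusted over the list alone, median 0.20, camera adjusted p = 1.4e-08, and adjusted p = 0.47 with an estimated correlation), and heat shock genes rose in 4 of 11 (6 higher and 1 lower when adjusted over the list alone, median 0.23, camera adjusted p = 0.015, and adjusted p = 0.76 with an estimated correlation). With the length and GC trend removed, the adjusted p by camera was 0.13 for oxidative phosphorylation and 0.097 for heat shock, and without the 5 doubted libraries it was 0.16 for heat shock. Genes with the same sign in each line and the smallest p included HINT1, a purine hydrolase (0.47 ± 0.05), the complex I subunits NDUFA8 (0.40 ± 0.05) and NDUFA12 (0.47 ± 0.06), and the endoplasmic reticulum proteins CNPY2 (0.52 ± 0.06) and CNPY3 (0.52 ± 0.06). On the lower side were the ubiquitin ligase RC3H2 (-0.62 ± 0.06), the kinase LMTK2 (-0.47 ± 0.05) and the receptor NOTCH2 (-0.52 ± 0.06).

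In the fit to all 40 libraries 18202 genes were tested, and edgeR called 2056 higher and 2477 lower in liver on average, 42 and 333 of them at least 2-fold. Of the 4533 called, 2513 had the same sign in each line, and 1837 also differed between lines in the interaction test. The calls rest on the mean of the same 4 effects, which favours equal signs. Taken line by line, 0 genes passed in the same direction in all 4 lines by edgeR, where RKO had 0 calls and 1775 unadjusted p under 0.05, and DESeq2 gave 5. In at least 3 lines 36 genes passed in the same direction, 20 higher and 16 lower, among them CNPY2, CNPY3, MRPL34 and ATP5IF1 on the higher side and LMTK2 and RC3H2 on the lower, and DESeq2 gave 186. An absolute log2 fold change of at least 1 left 2 of the 36, and an adjusted p under 0.01 left 0.

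Across genes, which are not independent replicates, the Pearson correlation of site fold changes was 0.27 between DLD1 and MDST8, 0.24 between RKO and Ls180, 0.17 between Ls180 and MDST8, 0.09 between RKO and MDST8, 0.05 between RKO and DLD1 and 0.04 between DLD1 and Ls180. No libraries are shared between lines. DLD1 and Ls180 had 226 genes higher in both, 192 lower in both and 134 in opposite directions, where 128, 120 and 249 are expected of independent calls. For DLD1 and MDST8 the numbers were 128, 128 and 49, where 62.7, 60.1 and 123 are expected. For Ls180 and MDST8 they were 56, 54 and 64, where 37.0, 33.3 and 70.4 are expected, so opposite calls were close to that number there.

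The response to the site also differed between lines. In an edgeR test of the interaction, 4721 of 18202 genes (25.9%) differed. ARFGEF3, a regulator of vesicle traffic, had log2 fold changes of -5.03 in MDST8, -1.06 in DLD1, 0.07 in RKO and 0.09 in Ls180 (adjusted p = 2.69e-10 by edgeR). The cytoskeletal gene EPB41L2 was at -1.08 in DLD1 and 0.60 in Ls180, the actin bundler PLS1 at -1.96 in MDST8 and 0.27 in Ls180, the RNA-binding gene RBPMS at -3.11 in Ls180 and 0.14 in RKO, and the chloride transporter CLCN3 at 0.85 in MDST8 and -0.69 in DLD1. Among gene lists, the site effect on hypoxia genes in Ls180 lay above that in the other lines for 17 of 24 members (22 when adjusted over the list alone, median difference 1.28, camera adjusted p = 6.1e-20, and adjusted p = 0.21 with an estimated correlation). For interferon genes it was higher in DLD1 than in the other lines for 16 of 22 (19 when adjusted over the list alone, median difference 1.70, camera adjusted p = 3.5e-08, and adjusted p = 0.81 with an estimated correlation). For antigen presentation it was lower in MDST8 for 9 of 11 (10 when adjusted over the list alone, median difference -0.94, camera adjusted p = 9.4e-13, and adjusted p = 0.11 with an estimated correlation). The interaction count was 9574 with limma-voom quality weights, 3096 with the hepatocyte score as a covariate and 8177 without the 5 libraries doubted above, and leaving out replicate 1, 2, 3 or 4 of every group gave 2438, 2986, 2377 and 2802.

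The lines themselves differed in more genes than the sites. Ls180 and DLD1 tumours expressed epithelial genes, and MDST8 and RKO tumours had most of them at lower levels. The adhesion molecule EPCAM was at 778 ± 149 CPM (n = 10) in Ls180, 814 ± 124 in DLD1 and 0.40 ± 0.25 in MDST8. The tight-junction gene CLDN7 was at 362 ± 85.6 CPM in Ls180, 1.29 ± 1.05 in RKO and 0.64 ± 0.44 in MDST8. All 15 epithelial genes were higher in DLD1 and in Ls180 than the mean log2 level of the other lines and all 15 lower in MDST8, while in RKO 13 were lower and 1 higher (but lower by mean CPM, 89.9 against 97.8), with the same counts when adjusted over the list alone. Camera gave adjusted p = 1.3e-10, 1.5e-08, 1.3e-07 and 7.9e-05 for these, and adjusted p = 0.22, 0.24, 0.17 and 0.44 with an estimated correlation.

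In Ls180 the immunoglobulin receptor PIGR was at 2679 ± 1378 CPM, the stem cell marker OLFM4 at 823 ± 639, the adhesion molecule CEACAM5 at 469 ± 273 and CDX1 at 175 ± 46.5, and 12 of 13 genes of intestinal identity were higher than in the other lines (camera adjusted p = 1.5e-08, and adjusted p = 0.16 with an estimated correlation). The Wnt pathway factor LEF1 was at 0.05 ± 0.07 CPM in Ls180 and at 133 ± 39.0 in DLD1. DLD1 had higher values for 12 of 14 Wnt targets (camera adjusted p = 1.9e-04, and adjusted p = 0.53 with an estimated correlation). ASCL2, a stem cell factor, was at 160 ± 50.03 CPM. The intestinal factor CDX2 was at 135 ± 31.9 CPM in DLD1.

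MDST8 expressed mesenchymal genes, with 13 of 15 higher and 2 lower than in the other lines (camera adjusted p = 3.7e-05, and adjusted p = 0.17 with an estimated correlation). N-cadherin CDH2 was at 286 ± 141 CPM in MDST8 and 0.60 in the mean of the other lines, the matrix protein SPARC at 817 ± 331 and 0.30, and the transcription factor SNAI2 at 125.8 ± 40.1 and 0.11. The Wnt inhibitor SFRP1 reached 1364 ± 721 CPM, against 0.11 in the others. CDX2 was at 0.02 ± 0.03 CPM in MDST8, and ribosomal proteins were lower in 24 of 24 cases (median -1.24, camera adjusted p = 1.2e-06, and adjusted p = 0.56 with an estimated correlation). RKO tumours had the growth factor HGF at 188 ± 79.0 CPM, AXL at 930 ± 157 and the transcription factor ZEB1 at 261 ± 47.5, and 17 of 22 interferon genes were lower than in the other lines and 1 higher (camera adjusted p = 0.01, and adjusted p = 0.75 with an estimated correlation). Counts for these lists were the same when adjusted over the list alone. Over 18202 genes edgeR called 6515 higher and 6527 lower in RKO, 6867 and 5274 in DLD1, 7076 and 5678 in Ls180, and 7569 and 7033 in MDST8. Tested against a fold change of 2, the totals were 4647, 4135, 4626 and 6675.

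Markers of host cell types were compared between sites, since the tumours grew in mouse tissue and only human genes were counted. The strict hepatocyte list summed to 3.58 ± 1.38 CPM in DLD1 liver tumours and 2.21 ± 0.67 in colon (exact two-sided permutation test, p = 0.0952), and to 2.09 ± 0.42 and 4.57 ± 2.20 CPM in Ls180 (exact permutation test, p = 0.0079, adjusted p = 0.0635), lower in each liver library than in any colon library. The wider hepatocyte list went the other way in MDST8, at 33.5 ± 4.75 CPM in colon and 43.2 ± 4.39 in liver, higher in each liver library (exact permutation test, p = 0.0079, adjusted p = 0.0635). In DLD1 the colonocyte list was at 70.7 ± 2.05 CPM in colon and 42.0 ± 13.3 in liver, and the macrophage list at 14.5 ± 2.64 and 8.83 ± 3.15 (exact permutation test, p = 0.0079, adjusted p = 0.0635 for each). This p is the smallest that 5 against 5 libraries can give. Of 32 such exact tests on 8 lists in 4 lines, 0 passed after adjustment, and so few libraries leave little room to pass, so this does not show that the lists were equal. The fibroblast list summed to 3910 ± 509 CPM in MDST8 colon tumours and 4300.0 ± 1910 in liver, with MMP2 its largest gene at 1670 CPM. In colon tumours of RKO, DLD1 and Ls180 it was at 4.41, 14.6 and 26.1 CPM. Its member SPARC, also on the mesenchymal list, was at 817 CPM in MDST8 and 0.30 in the mean of the other lines. In MDST8 the fibroblast list thus need not measure host fibroblasts.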

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

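The tests of gene length or GC bias, of a swap of labels, of mitochondrial reads and of mitochondria-rich libraries were chosen only after the result was seen; those of library size, host macrophages and other splits of the libraries were not.

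In DLD1, fold changes fell with gene length, and this pattern held ribosomal and respiratory genes but not interferon or intestinal genes. A difference in library size is argued against, since the Spearman correlation with length was -0.587 after all libraries were thinned to 4.29 M counts. With each library's length and GC trend removed, the larger absolute median of the ribosomal and oxidative phosphorylation lists was 0.111 (medians 0.363 ± 0.173, SD over genes, to -0.111 ± 0.252, and 0.405 ± 0.275 to 0.039 ± 0.203), so a length or GC bias may account for these lists. The interferon and intestinal lists kept at least 1.06 times their medians, which argues against that bias for them. All 5 colon slopes on length were positive (0.091 to 0.191) and all 5 liver slopes negative (-0.191 to -0.038), so RNA quality, library preparation and site remain open and untested.

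In Ls180, colon replicate 2 and liver replicate 1 lay toward the other site, and leaving both out gave 5709 genes instead of 2241. A swap of their labels is argued against by the position of liver replicate 1, 0.475, where the other colon libraries lie at 0.002 to 0.162. Colon replicate 2, at 0.574, lay outside the 0.764 to 1.025 of the other liver libraries, but by less than the largest gap among those. By the rule used it does not argue against a swap, and the rule asked this of only 1 of the 2 libraries. Exchanging the 2 labels nevertheless gave 4948 genes, more than the 2241 of the labels as given. Length or GC bias is argued against by the smaller distance from the own site, 0.517 after its removal. A mitochondrial takeover of both is argued against by the 2.466% share of liver replicate 1, under the 3.575% to 5.108% of the other liver libraries, while leaving out mitochondrial genes moved neither position (0.574 and 0.475) and decides nothing. A mixture of tissue from both sites and a biological difference between samples were not tested.

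In MDST8, the NF-kB targets were lower in liver. Length or GC bias is argued against, since 1.024 of the median was kept after its removal. The macrophage list's fall was 0.0498 of that of the NF-kB list (42.3 and 849 CPM), the outcome foreseen if host macrophages were not the source. This cannot exclude host macrophage reads. The largest gene of the macrophage list was CD68, at 71.3 CPM in MDST8 and 732 in RKO, so the list need not measure macrophages. Libraries rich in mitochondrial reads are argued against, since 1.18 of the median was kept without liver replicates 1 and 2 (-1.934 to -2.283). A lower inflammatory signal in the tumour cells at the liver site may explain the lower NF-kB targets. This hypothesis was found in the same data, was not tested and is inseparable from the route of implantation.

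Other splits of the same libraries cannot exclude a batch or preparation that goes with site. Nor can they exclude a difference between few tumours if the replicates are technical. They show only where a chance assignment of these libraries to sites can be excluded. For genes it can be excluded in DLD1 (1 of 100 splits gave as many; 3554, highest other 620), MDST8 (1 of 100; 1270, highest other 20) and Ls180 (2 of 100; 2241, highest other 4948). The split with 4948 genes exchanges colon replicate 2 with liver replicate 1 and points to a structure of the samples. Such a chance assignment can also be excluded for the mean (1 of 36 splits, 4533 genes, highest other 1776). For differences between lines (1 of 36, 4721 genes, highest other 3382) the splits exclude only chance in the absence of any site effect. They remove the site effect from every line, so equal site effects in all lines were not tried. Against the other lines the real split also gave the most genes. The counts were 13042 in RKO (1 of 36, highest other 842) and 12141 in DLD1 (1, highest other 19). They were 12754 in Ls180 (1, highest other 452) and 14602 in MDST8 (1, highest other 2399). Those splits mix libraries of different cell lines, so this shows only that the lines differ. For genes in RKO the splits decide nothing, since any split has at least 0 genes (100 of 100; 0 by edgeR, highest other 0, with 1775 genes at an unadjusted p under 0.05, 266 by DESeq2 and 0 by limma-voom). There, 443 genes (3.1%) had no overlap between sites, where 0.79% is expected on average over all splits. Genes without overlap were not counted in the other splits, so chance is not excluded for them. It cannot be excluded for the number of lists in RKO (76 of 100; 4, highest other 13), DLD1 (82; 5, highest other 17), Ls180 (43; 13, highest other 22), MDST8 (9; 12, highest other 15) or the mean (20 of 36; 7, highest other 13).

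In 31 of 394 groups of 5 libraries, 1 library lay far from the other 4 by its gap over the range, and chance alone gives about 1 in 20 groups. Among library measures these were DLD1 colon replicate 2 in total (0.751; 7.6 M against 22.1 to 26.9), mitochondrial share (0.829; 6.682% against 4.168 to 4.599), share of the top 10 genes (0.865; 6.62% against 4.62 to 4.89) and genes with a read (0.88; 18391 against 20570 to 20867). DLD1 liver replicate 5 stood apart in mitochondrial share (0.752; 16.146% against 3.469 to 6.619) and top 10 genes (0.78; 15.19% against 4.38 to 6.76), and liver replicate 1 in genes with a read (0.776; 17390 against 18893 to 19328). Ls180 colon replicate 2 stood apart in mitochondrial share (0.738) and top 10 genes (0.782; 7.41% against 4.79 to 5.36).

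Among lists and genes, in log2 CPM, RKO colon replicate 4 stood apart in the cholesterol synthesis list (0.745), HSPD1 (0.717) and STARD4 (0.846), DLD1 colon replicate 2 in IFIT1 (0.719), GPRIN3 (0.774) and RPS9 (0.832), and DLD1 liver replicate 4 in IFI27 (0.819; 0.459 against 5.331 to 6.405). In Ls180 these were colon replicate 2 in the immediate early list (0.8), GPR15LG (0.727) and LATS2 (0.815), colon replicate 5 in the heat shock list (0.877) and SP5 (0.739), colon replicate 4 in CALD1 (0.769), and liver replicates 4, 5 and 3 in CDH17 (0.784), HK2 (0.773) and HSPE1 (0.806). In MDST8 these were colon replicate 5 in CXCL3 (0.786; 7.485 against 3.828 to 4.61), ID3 (0.759) and ACTG2 (0.824; 2.816 against 7.327 to 8.289), colon replicate 4 in PGK1 (0.74), and liver replicate 5 in IL1B (0.828) and ROBO4 (0.884).

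The site effect differed between lines for 4721 genes by edgeR's interaction test, with the smallest adjusted p for ARFGEF3 and EPB41L2 (2.69e-10 each), OSBP2 (5.31e-09), PLS1 (6.01e-09), CCDC69 and CLCN3 (2.77e-08 each), DENND4C (3.6e-08), RBPMS (1.71e-07), ME3 (1.75e-07) and APH1B (1.78e-07). For lists, camera compared the site effect of a line with the mean of the others. It was lower in RKO for oxidative phosphorylation (adjusted p = 0.0041) and ribosomal proteins (1.1e-05). In DLD1 it was lower for intestinal identity (0.001) and hypoxia (6.2e-06) and higher for oxidative phosphorylation (7.8e-04), interferon (3.5e-08), antigen presentation (1e-05) and NF-kB (0.0018). In Ls180 it was higher for intestinal identity (0.0056), hypoxia (6.1e-20), glycolysis (8.5e-07), ribosomal proteins (0.012), unfolded protein response (2e-06) and heat shock (0.0023), and lower for mesenchymal genes (0.0021), YAP targets (0.0012) and p53 targets (0.041). In MDST8 it was lower for endothelial genes (0.0097), hypoxia (1.7e-04), glycolysis (3.6e-05), proliferation (1.1e-04), interferon (4.5e-05), antigen presentation (9.4e-13), NF-kB (4.5e-05) and acute phase genes (0.044), and higher for TGF-beta and BMP targets (0.0028) and p53 targets (0.011). With an estimated correlation the smallest adjusted p among these was 0.11. Gene identifiers without a symbol held 0.441% of all counts, and none of them was named.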

How the results depend on the processing

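The tests with the length or length and GC trend removed, without the doubted libraries, with the authors' size factors, without mitochondrial genes, and the shared-gene counts at 3 lines or by DESeq2 were chosen only after the result was seen. Counts of changed genes moved by over 1.5 times as follows, and the cause was not tested. RKO (0 by edgeR, 1775 at an unadjusted p under 0.05, 0 by limma-voom) gave 266 with DESeq2, 23 in the 40-library fit and 1 with the replicate block. DLD1 (3554) gave 2025 with the replicate block, 1709 with the hepatocyte covariate, 1964 without the length and GC trend, 1206 without the length trend and 5527 without its doubted library. Ls180 (2241) gave 45 with the covariate, whose list was lower in each liver library there. It gave 5709 without the doubted libraries and 5068 with the trend also removed. MDST8 (1270) gave 2475 with DESeq2, 2874 in the 40-library fit, 817 with the replicate block, 1952 without the trend and 844 without the doubted libraries. The interaction count (4721) was 9574 with quality weights, 3096 with the covariate and 8177 without the doubted libraries. The mean and the 4 line counts stayed within 1.5 times under each alternative run for them. Genes shared by 4 lines (0) were 5 with DESeq2, and those shared by at least 3 (36) were 0 at an adjusted p of 0.01, 2 with a log2 fold change of at least 1 and 186 with DESeq2.

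Leaving out 1 library or replicate number also moved some counts by over 1.5 times, by a cause not tested. Leaving out 1 library gave 0 to 1 genes in RKO, 2025 to 5527 in DLD1, 908 to 4169 in Ls180 and 646 to 2629 in MDST8. Leaving out a replicate number gave 3252 to 4308 for the mean, 2377 to 5292 for the interaction, and for the lines 12270 to 12724 (RKO), 11177 to 11807 (DLD1), 11819 to 12410 (Ls180) and 13970 to 14250 (MDST8). List counts ran over 4 to 7 (RKO), 4 to 7 (DLD1), 11 to 15 (Ls180), 10 to 13 (MDST8) and 6 to 10 (mean). Correlations ran over 0.022 to 0.089 (RKO and DLD1), 0.203 to 0.26 (RKO and Ls180), 0.066 to 0.103 (RKO and MDST8), 0.016 to 0.085 (DLD1 and Ls180), 0.174 to 0.303 (DLD1 and MDST8) and 0.122 to 0.209 (Ls180 and MDST8).

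By camera with an estimated correlation, fry, and fry in either direction, the numbers of lists were 0, 0 and 7 in RKO (4), 0, 1 and 20 in DLD1 (5), and 0, 7 and 21 in Ls180 (13). In MDST8 (12) camera with an estimated correlation gave 0 and fry in either direction 19, and for the mean (7) the former gave 0 and fry 16. Spearman correlations were 0.079 for RKO and DLD1, 0.265 for RKO and Ls180, 0.096 for DLD1 and Ls180, 0.32 for DLD1 and MDST8 and 0.237 for Ls180 and MDST8. Over genes called in either line Pearson was 0.133, 0.351, 0.119 and 0.317 for RKO with DLD1, Ls180 and MDST8 and for DLD1 with MDST8, and with the trend removed 0.011 for RKO and DLD1 and 0.145 for Ls180 and MDST8. The cause was not tested.

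In 2 cases a sign reversed, both in DLD1. The ribosomal list had a camera adjusted p = 0.43 with the length and GC trend removed. RPL27 went to -0.003 ± 0.13 with the trend removed and the doubted library left out, where removal of the trend alone gave 0.088, and the cause of this reversal was not tested. Of the values of named genes, 744 of 818 in DLD1, 1179 of 1395 in Ls180, 1045 of 1168 in MDST8 and 712 of 720 for the mean kept direction and side of the threshold, and the others, apart from RPL27, kept direction only. Losses gathered in MDST8 without the doubted libraries (22 of 47 genes) and in Ls180 with the covariate (49 of 56). In RKO 6 of 248 passed, all 6 with DESeq2.

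Expression gave little sign that replicate numbers pair the libraries. Correlations of same-numbered libraries ran from -0.466 to 0.413, and the own number was the best match for 2, 0, 1 and 1 of 5 libraries. This cannot exclude a shared animal or batch, which the labels do not give. For depth, 3 counts are 0.119 to 0.178 CPM in MDST8, 0.129 to 0.257 in Ls180 and 0.112 to 0.699 in DLD1. Genes below this have no usable fold.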

Other observations

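No alternative or test in this part was chosen only after the result was seen, but PDK4, PPARGC1A and UGT1A6 were chosen after their values were seen. In Ls180, 3 of 15 genes of the fatty acid oxidation list rose and 2 fell. The 2 were PDK4 and PPARGC1A. PDK4, which restrains glucose oxidation, fell from 8.51 ± 1.08 to 1.84 ± 0.52 CPM, and PPARGC1A, a coactivator of mitochondrial genes, fell from 16.1 ± 6.69 to 6.33 ± 2.28. UGT1A6 rose from 12.3 ± 3.14 to 96.5 ± 54.4 CPM, but shares exons with UGT1A1.

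Targets of the xenobiotic receptors PXR and CAR, fatty acid oxidation and fatty acid synthesis passed camera in no line, whereas cholesterol synthesis passed in RKO (adjusted p = 0.0012, and 0.92 with an estimated correlation). For the PXR and CAR targets the adjusted p was 0.82 in RKO, 0.78 in DLD1, 0.34 in Ls180 (3 of 9 higher, 1 lower) and 0.64 in MDST8, with medians of -0.01, 0.04, 0.13 and -0.17. For the bile acid list, tested in DLD1 and Ls180 with 3 genes each, it was 0.96 and 0.79. For fatty acid oxidation it was 0.41, 0.79, 0.23 (3 of 15 higher, 2 lower) and 0.87, and for fatty acid synthesis 0.65, 0.08 (3 of 12 lower), 0.17 and 0.44. A p that misses the threshold does not show that these genes were equal.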
